A study of Staphylococcus aureus with 4 samples.

How the data were processed

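The deposited table covered Staphylococcus aureus ATCC29213, a standard laboratory strain, grown as 48 h biofilms at 37 °C in tryptic soy broth with 0.25% glucose. Per the labels, biofilms were exposed for 60 min to tea tree oil (TTO), an essential oil with antimicrobial activity, at 1 mg/ml. That dose was 1/2 of the minimal biofilm inhibitory concentration, and the oil was dissolved in dimethyl sulfoxide (DMSO). Control biofilms received 0.1% DMSO. RNA was extracted with a silica-column kit, treated with DNase I and made into Illumina TruSeq libraries, per the labels' protocols. The 4 libraries formed 2 groups of 2, control and TTO. The control columns carried the codes of the control samples. Both TTO columns began with the code of 1 TTO sample (D1-1 and D1-2), so they were placed in the TTO group without being tied to a single sample, and may be 2 libraries of 1 culture.

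Read counts per gene were taken as the authors deposited them, as whole numbers that per the file headers are reads. The deposited RPKM columns, named so per the file headers, were not used for any result given here. They were first used in alternatives that were later replaced. As with the counts, those of TTO cannot be tied to single samples. The aligner was Bowtie2, per the submitters' processing notes. Its version, the counting tool, its strand setting and the genome build are not given in the sources used here. Counting strand was therefore unknown, so overlapping genes, antisense genes and near-identical copies are uncertain. Locus tags and coordinates were those of the file, which uses the chromosome and plasmid of strain N315, another strain than the one sequenced. Genes that only ATCC29213 carries were not analysed here. In all, 8 columns were not used for any result given here, the 4 with RPKM per library and the group means. No genome sequence was used here, so GC content was not checked.

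The table listed 2860 features, 2832 on the chromosome and 28 on the plasmid. Library totals ranged from 25892131 to 26928003 reads, with a median of 2198 to 2388 reads per feature. In all 4 libraries, 107 features had 0 reads; a count of 0 allows up to 3 counts, or 0.111 to 0.116 CPM (a gene's reads scaled to the library total) per library, for counting error only. Such floors do not cover the spread between cultures.

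The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts with TMM scaling, comparing TTO with control over all 4 libraries with no covariate. Features were tested when they passed edgeR's expression filter at its defaults (minimum count 10, minimum total count 15), which kept 2681. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and the standard error (SE) of a log2 fold change was its size divided by the square root of F. CPM values were scaled by TMM and are given as mean ± SD. Gene lists were tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, over lists with at least 3 tested members. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera rests on the residual degrees of freedom. With 2 libraries per group these are few, so that setting had little power here. No label named a batch, date or lane, so no comparison within batches was made.

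The design, the 33 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Lists were matched through gene identifiers, protein names and product descriptions in the table; the pairs of symbol and product were written after the annotation, but before any test result, had been seen. Of the table's locus tags, 0 matched the annotation table of another strain that was at hand, and 59 gene identifiers did, so names came from the deposited table alone. The lists covered pyrimidine synthesis, purine synthesis, heat shock and proteolysis, cell wall stress (VraSR), oxidative and thiol stress, autolysins and holins, adhesins and biofilm matrix, agr system, toxins and exoenzymes, virulence and stress regulators, SigB regulon markers, capsule, fatty acid and phospholipid synthesis, glycerol and glycerolipid metabolism, ribosomal proteins, aminoacyl-tRNA synthetases, glycolysis and gluconeogenesis, fermentation, arginine deiminase pathway, nitrate and nitrite reduction, TCA cycle, respiratory chain and ATP synthase, branched-chain amino acid synthesis, lysine, threonine and methionine synthesis, histidine synthesis, arginine, proline and glutamate metabolism, aromatic amino acid synthesis, urease, iron acquisition, efflux pumps and antimicrobial peptide response, DNA repair and SOS, osmoprotection and potassium transport, peptidoglycan synthesis and cell division and stable RNAs.

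The rule named, among called genes at a mean of at least 10 CPM whose libraries did not overlap between groups and which had a symbol, the 8 largest rises and the 8 largest falls. It added the 3 called members of each list with the largest changes, and icaA, icaR, sigB, sarA, agrA and saeR whatever their values. The last 3 could not be identified from the table's text. A symbol was read as a gene identifier or a capitalised protein name in the description, so names in lower case, such as protein msa (SA1233), were missed. A looser reading, in which symbols matched through product descriptions also counted, was run first and its output was seen; the stricter reading was adopted afterwards because it is the literal wording of the rule. The rule named 105 genes, of which 33 overlapped another feature on the same strand and 1 (ptsG) on the opposite strand.

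The tests were checked on simulated counts drawn from the real genes' means, library sizes and fitted dispersions. Recovery thus holds for the spread between these libraries, and says nothing about the spread between separate cultures. For TTO against control, over 2676 genes, 52 of 65 genes changed by 0.5 on the log2 scale were called, 66 of 67 changed by 1, and 67 of 67 changed by 2, while 10 of 2477 unchanged genes were called. With no gene changed, over 2679 genes, 0 genes and 0 of 33 lists were called. With the purine genes doubled, that list alone was called. Genes were drawn independently of each other, so the simulation could not show false list calls that come from correlation between genes. In the real data the estimated correlation within lists ran from -0.152 (arginine deiminase pathway) to 0.985 (urease).

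Alternatives were other scalings (RLE, upper quartile, total count), no filter, a filter at a mean of 10 CPM, DESeq2 1.42.0, limma-voom, limma with trend on log2(RPKM + 1) and log2(RPKM + 0.1) over genes at 1 RPKM or more in 2 libraries, and each library left out in turn. Further ones were an estimated correlation for the lists, a test against a 2-fold change, an adjusted p below 0.01, and other settings of the correlation between libraries. Removal of a trend with gene length was added after the data had been seen. The fits on RPKM had been set for the deposited RPKM and were run on them, with the results seen. They were then replaced by fits on RPKM computed from the deposited counts, locus length and library total, so those fits too were added after the data had been seen.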

Results

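RNA sequencing measured the transcripts of mature S. aureus biofilms after 60 min with TTO at 1 mg/ml, against biofilms given DMSO alone, to ask how the oil changes gene expression in a biofilm. There were 2 libraries per group. Totals were 26291451 and 26928003 reads in the controls and 25892131 and 26543814 reads with TTO. Log2 CPM correlated across 2681 genes at r = 0.997 between the controls, 0.998 between the TTO libraries and 0.961 to 0.965 between groups, where genes are not independent replicates. The median absolute log2 difference per gene was 0.10 between the controls, 0.05 between the TTO libraries and 0.39 to 0.42 between groups. Counts of the paired libraries differed by more than sampling noise, with chi-square per degree of freedom of 46.4 in the controls and 6.70 with TTO, so no pair was treated as 1 library deposited in duplicate. Separate preparations of 1 culture would exceed that noise too. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Below, a log2 fold change is TTO over control with its SE after ±, and CPM are mean ± SD (n = 2 per group).

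By camera, lists of nitrate respiration, biofilm adhesion, secreted toxins, synthesis of branched-chain amino acids, histidine and nucleotides, and metabolism of arginine, proline and glutamate shifted up with TTO, and urease and regulators down. Each of these lists had adjusted p = 0.640 with an estimated correlation, a setting with little power at 2 libraries per group. Of the 2681 genes tested, 947 rose and 939 fell, together 70.3%. TMM scaling assumes that most genes do not change, and the median log2 fold change was 0.002. Rises and falls are thus relative to the other genes, and a shift of all transcripts together would not be seen. At least 2-fold changes were seen for 247 of the genes that rose and 112 of those that fell, and 4-fold changes for 45 and 9. Among genes at a mean of at least 10 CPM whose symbol or capitalised protein name was read from the table, the 8 largest rises were icaD (SA2460, 2.79 ± 0.14), narZ (SA2185, 2.74 ± 0.05), narH (SA2184, 2.55 ± 0.05), narT (SA2176, 2.41 ± 0.10), murQ (SA0185, 2.33 ± 0.19), sdrE (SA0521, 2.11 ± 0.06), glnQ (SA1674, 2.06 ± 0.09) and lrgB (SA0253, 2.00 ± 0.09). Among these, murQ encodes an etherase that recycles cell wall amino sugars, glnQ an amino acid transport ATPase and lrgB an antiholin-like protein. The 8 falls named by the same rule were ureD (SA_RS11995, -1.31 ± 0.08), fdhD (SA2075, -1.18 ± 0.09), gpmA (SA2204, -1.09 ± 0.06), ftsL (SA1023, -1.07 ± 0.04), ureE (SA2085, -0.99 ± 0.07), rpsP (SA1081, -0.99 ± 0.05), icaR (SA2458, -0.97 ± 0.06) and relB (SA2195, -0.96 ± 0.05). Genes named from their product alone, such as putA, glpF, lip and icaA, had larger rises and stand with their lists. SA1233, described as protein msa in lower case and so not read as a symbol, fell further (-2.05 ± 0.10) and was named after its value was seen. Here fdhD encodes an accessory protein of formate dehydrogenase, gpmA a phosphoglycerate mutase, ftsL a cell division protein, rpsP ribosomal protein S16 and relB an antitoxin. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment these 16 genes had adjusted p from 8.69e-07 to 6.22e-05. In 2336 of the 2681 genes (87.1%) the groups did not overlap, where chance gives 33.3% for 2 against 2. A test against a 2-fold change itself, in place of a 2-fold line on the estimate, left 186 genes in place of 359.

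The genes of nitrate and nitrite reduction, which let S. aureus use nitrate as an electron acceptor when oxygen is short, rose together: 7 of 7 rose, also when adjusted over the list alone, with a median of 2.31. The nitrate reductase gene narZ (chromosome, 2452713 to 2456402) went from 169 ± 5.15 to 1128 ± 16.9 CPM and narH (chromosome, 2451164 to 2452723) from 96.6 ± 3.97 to 565 ± 4.15 CPM. The nitrate transporter gene narT (chromosome, 2444291 to 2445460) went from 80.5 ± 12.4 to 428 ± 0.581 CPM. The nitrite reductase genes nirB (1.61 ± 0.04) and nirD (1.51 ± 0.05) and the nitrate reductase genes narJ (2.31 ± 0.06) and narI (0.83 ± 0.05), named after their values were seen, completed the list. Camera gave adjusted p = 0.00104 for the list (adjusted p = 0.640 with an estimated correlation). The tags of its members lie close together (SA2176 to SA2188), so they may be few joint changes.

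**Figure D1:**
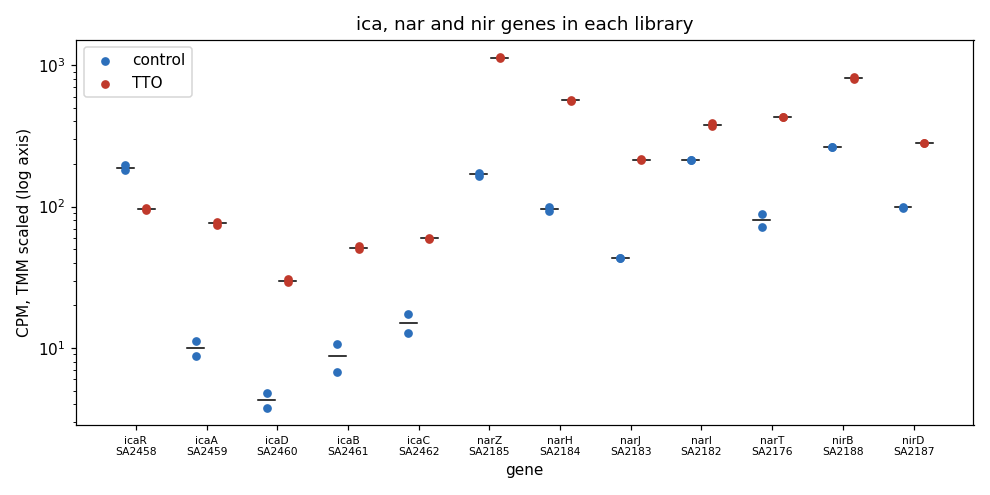
CPM, TMM scaled, on a log axis, for the ica, nar and nir genes in each library, with control in blue, TTO in red and a bar at each group mean (n = 2). Only icaR lay lower with TTO, at 96.7 against 189 CPM, and icaA went from 9.99 ± 1.77 to 76.0 ± 2.24 CPM (mean ± SD).

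Adhesin and biofilm matrix genes rose, with 14 of 19 higher, 2 lower and 3 not past the test, and the same counts when adjusted over the list alone. The widest changes were in the ica operon, whose enzymes make the polysaccharide intercellular adhesin of the biofilm matrix. The synthase gene icaA (SA2459, chromosome, 2770497 to 2771735) rose from 9.99 ± 1.77 to 76.0 ± 2.24 CPM, a log2 fold change of 2.93 ± 0.12 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 5.35e-06). The adjacent icaD (chromosome, 2771699 to 2772004) rose from 4.30 ± 0.719 to 29.9 ± 1.11 CPM, and icaB (SA2461, 2.56 ± 0.19), for a deacetylase of that polymer, rose too. Their repressor gene icaR (chromosome, 2769773 to 2770333, on the opposite strand) fell by 0.97, from 189 ± 9.78 to 96.7 ± 2.15 CPM. The surface adhesin gene sdrE (chromosome, 612994 to 616419) rose by 2.11 ± 0.06. The other member that fell was sraP (-0.50 ± 0.07), for a platelet-binding adhesin, named after its value was seen. The list's adjusted p was 0.0125 by camera (adjusted p = 0.640 with an estimated correlation). Adjacent ica genes overlap on the same strand, and the sdr genes share repeats, so their separate values are uncertain.

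Secreted toxins and enzymes rose while 3 genes of the agr quorum-sensing locus fell. In the list of the agr system, toxins and exoenzymes, 21 of 28 rose, 3 fell and 4 did not pass, as also when adjusted over the list alone. Those that rose include the staphylokinase gene sak (SA1758, 1.23 ± 0.13), named after its value was seen, which is also counted in the prophage described below. The lipase gene lip (SA2463) rose from 23.2 ± 1.39 to 169 ± 1.41 CPM, the pore-forming gamma-hemolysin gene hlgA (SA2207) from 4.78 ± 0.503 to 31.4 ± 0.300 CPM, and the serine protease gene splB (SA1630) from 1.37 ± 0.670 to 3.85 ± 0.189 CPM. The 3 that fell were hld (-0.97 ± 0.12), agrB (-0.82 ± 0.06) and agrD (-0.71 ± 0.06), named after their values were seen; hld encodes delta-hemolysin, agrD a signal peptide and agrB its processing enzyme. The list passed camera at adjusted p = 0.00188 (adjusted p = 0.640 with an estimated correlation). Of the regulator list only 5 members could be identified, and 5 of 5 fell, also adjusted over the list alone. These were rsbW (SA1870, -0.80 ± 0.05), sigB (SA1869, chromosome, 2118150 to 2118920, -0.51 ± 0.04) and rsbV (SA1871, -0.47 ± 0.05) of the general stress sigma factor operon, and the metabolic regulators ccpA (-0.35 ± 0.04) and codY (-0.21 ± 0.04), of which the last 2 were named after their values were seen. That list had adjusted p = 0.0373 (adjusted p = 0.640 with an estimated correlation), and its call ended without TTO library D1-1 (0.0572) or without D1-2 (0.0649), in a range of 0.0216 to 0.0649 over the alternatives. By fry, which does not compare a list with other genes, the SigB regulon markers were called (adjusted p = 0.0126). These markers, which include sigB, rsbW and rsbV themselves, went both ways, with 4 of 12 higher, 5 lower and camera adjusted p = 0.709. Among them crtO (SA2352, -0.51 ± 0.15), for staphyloxanthin pigment synthesis, lost its call without D1-2 (-0.43, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.134) and with DESeq2 (-0.52, adjusted p = 0.0736).

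Nucleotide synthesis genes rose. In pyrimidine synthesis 8 of 9 rose, led by the uracil permease gene pyrP (SA1042, 1.65 ± 0.06), pyrC (SA1044, 1.61 ± 0.06) and pyrB (SA1043, 1.59 ± 0.06), while the regulator gene pyrR (SA1041), named after its value was seen, fell by 0.61. In purine synthesis 11 of 15 rose, 1 fell and 3 did not pass, with purQ (SA0920) going from 9.59 ± 0.401 to 33.5 ± 0.726 CPM, purS (SA0919) at 1.48 ± 0.17 and purC (SA0918) at 1.38 ± 0.12; the member that fell, purB (-0.37 ± 0.05), was named after its value was seen. The counts were the same when adjusted over the list alone. Most members carry consecutive tags (SA1041 to SA1048 and SA0916 to SA0926), so they may be few joint changes. The estimated correlations, 0.684 for pyrimidine and 0.367 for purine synthesis, lie above the preset 0.01. Both lists had adjusted p = 0.00634 by camera (adjusted p = 0.640 with an estimated correlation).

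Genes of amino acid synthesis and use rose in 3 lists. In branched-chain amino acid synthesis and uptake 10 of 11 rose and 0 fell, with ilvD (SA1858) from 24.2 ± 1.44 to 86.0 ± 2.49 CPM, the transporter gene brnQ (SA0180) from 62.7 ± 1.69 to 192 ± 1.32 CPM and ilvC (SA1861) from 19.2 ± 3.75 to 47.7 ± 0.926 CPM; camera gave adjusted p = 0.00188 (adjusted p = 0.640 with an estimated correlation). In histidine synthesis 9 of 9 rose, with hisG (SA2471, 1.79 ± 0.17), hisD (SA2470, 1.48 ± 0.12) and hisZ (SA2472, 0.94 ± 0.12), at adjusted p = 0.00716 (adjusted p = 0.640 with an estimated correlation). In arginine, proline and glutamate metabolism 9 of 17 rose, 4 fell and 4 did not pass, at adjusted p = 0.0484 (adjusted p = 0.640 with an estimated correlation). The proline dehydrogenase gene putA (SA1585, chromosome, 1823844 to 1824845), whose product starts proline breakdown, went from 5.35 ± 1.42 to 162 ± 3.23 CPM, a log2 fold change of 4.92 ± 0.14 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.86e-06). The arginine synthesis genes argG (SA0822, 2.72 ± 0.08) and argH (SA0821, 2.47 ± 0.11) rose as well. Counts adjusted over the list alone were the same for these 3 lists. Most histidine genes (SA2464 to SA2472) and most branched-chain genes (SA1858 to SA1866) carry neighbouring tags, so they may be few joint changes. The call of the arginine, proline and glutamate list ended without control 1 (0.131), with upper-quartile scaling (0.0501), above a mean of 10 CPM (0.0506) and with a length trend removed (0.105), in a range of 0.0267 to 0.131.

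The urease operon, whose enzyme releases ammonia from urea, fell: 7 of 7 genes fell, also adjusted over the list alone, with a median of -0.83. The accessory gene ureD (chromosome, 2347072 to 2347908) went from 1867 ± 204 to 752 ± 1.95 CPM, ureC (SA2084), for the catalytic subunit, from 2618 ± 245 to 1245 ± 5.97 CPM, and ureE (chromosome, 2345311 to 2345763) from 1361 ± 139 to 684 ± 0.0819 CPM. Camera gave adjusted p = 0.00647 (adjusted p = 0.640 with an estimated correlation).

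Many central carbon genes changed, but their lists did not pass camera. Fry, which does not compare a list with other genes, called each of them, at adjusted p from 0.000378 (glycolysis) to 0.0174 (TCA cycle). In glycolysis 10 of 18 rose and 4 fell (10 and 5 adjusted over the list alone; camera adjusted p = 0.119), with the glucose transporter gene ptsG (SA0183, 1.44 ± 0.09), pgk (SA0728, 1.33 ± 0.05) and tpiA (SA0729, 1.32 ± 0.05) among those that rose. In fermentation 5 of 11 rose and 5 fell (adjusted p = 0.990); the alcohol dehydrogenase gene adhE (SA0143, 1.94 ± 0.13), the lactate dehydrogenase gene ldh (SA0232, 1.61 ± 0.10) and the pyruvate formate-lyase gene pflB (SA0218, 1.52 ± 0.07) rose. The anaerobic ribonucleotide reductase genes nrdD (SA2410, -1.29 ± 0.06) and nrdG (SA2409, -1.24 ± 0.05) and the acetoin synthesis gene budA (SA2007, -1.23 ± 0.10), named after their values were seen, fell. The fermentation median (-0.36) was below 0 while its mean (0.20) and test were above. Glycerol and glycerolipid genes rose in 10 of 15 cases and fell in 4 (adjusted p = 0.119), with the glycerol channel gene glpF (SA1140) from 17.7 ± 3.29 to 252 ± 0.840 CPM, glpT (SA0325, 2.40 ± 0.09) and the kinase gene glpK (SA1141, 1.67 ± 0.05). In the respiratory chain and ATP synthase 13 of 23 rose and 4 fell (adjusted p = 0.154), with the cytochrome bd oxidase genes cydB (SA0938, 1.46 ± 0.08) and cydA (SA0937, 1.34 ± 0.06) and the ATP synthase gene atpE (SA1910, 0.72 ± 0.05) rising. In the TCA cycle 9 of 13 rose and 1 fell (adjusted p = 0.0837), led by fumC (SA1669, 0.79 ± 0.07), acnA (SA1184, 0.74 ± 0.05) and sucD (SA1089, 0.68 ± 0.05). Of the arginine deiminase pathway, which yields ATP from arginine, 4 of 7 fell and 0 rose (adjusted p = 0.0807), among them an ArgR family regulator gene (SA2429, -1.19 ± 0.12), argF (SA1012, -0.74 ± 0.08) and arcC (SA1013, -0.57 ± 0.08).

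Envelope and drug-response genes gave further single changes, and none of their lists passed camera. Fry called the efflux (adjusted p = 0.00466), osmoprotection (0.000378), autolysin (0.00426), fatty acid (0.00119) and cell wall stress (0.0263) lists. It did not call peptidoglycan synthesis (0.0667) or capsule (0.360). Of the efflux pumps and antimicrobial peptide response 9 of 11 rose and 2 fell (adjusted p = 0.0515); the genes described as the quinolone efflux pump NorB that rose most were SA2233 (1.20 ± 0.07), SA1269 (1.18 ± 0.05) and SA0263 (1.01 ± 0.18), related copies whose reads may be shared. Among osmoprotection and potassium transport genes 7 of 9 rose and 1 fell (adjusted p = 0.0598), with the choline dehydrogenase gene betA (SA2405, 1.09 ± 0.11) and the potassium pump genes kdpC (SA1879, 0.96 ± 0.15) and kdpA (SA1881, 0.82 ± 0.16). Of autolysins and holins 6 of 10 rose and 3 fell (adjusted p = 0.358), with the antiholin-like genes lrgB, from 18.9 ± 2.09 to 75.3 ± 1.61 CPM, and lrgA (SA0252, 1.58 ± 0.11) and the transglycosylase gene sceD (SA1898, 1.40 ± 0.06). In fatty acid and phospholipid synthesis 9 of 21 rose and 5 fell (adjusted p = 0.230), with fabF (SA0843, 1.02 ± 0.04), cls (SA1155, 0.93 ± 0.07) and fabH (SA0842, 0.90 ± 0.05). In peptidoglycan synthesis and cell division 11 of 27 rose and 7 fell (adjusted p = 0.990), with ftsL, murI (SA0997, -0.69 ± 0.05) and an ftsW gene (SA1888, -0.54 ± 0.05) falling most; its mean (-0.03) was below 0 while its median (0.02) and test were above. Of the 6 cell wall stress genes matched, 1 rose and 3 fell (adjusted p = 0.519), namely the msrA genes SA1257 (0.55 ± 0.04) and SA1194 (-0.30 ± 0.05), prsA (SA1659, -0.24 ± 0.04, named after its value was seen) and fmtA (SA0909, -0.71 ± 0.10). In the capsule list 3 of 11 rose and 1 fell (1 and 0 adjusted over the list alone; adjusted p = 0.519), with cap5B (SA0145, 0.43 ± 0.14), cap8F (SA0149, 0.43 ± 0.12) and capA (SA2457, -0.60 ± 0.18). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the calls of cap5B and capA ended without control 2 (0.28, adjusted p = 0.0850, and -0.47, 0.0870) and without TTO library D1-1 (0.33, 0.110, and -0.54, 0.108). Calls also ended at -0.61 for capA with DESeq2 (adjusted p = 0.0904), 0.40 for cap5B with total-count scaling (0.0656), 0.29 for cap8F with the length trend removed (0.0660), and for cap5B and cap8F in limma on log2(RPKM + 1) (0.40, 0.0758, and 0.40, 0.0578) and log2(RPKM + 0.1) (0.41, 0.0769, and 0.41, 0.0584).

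The lists of stress, repair, translation, iron and 2 groups of amino acids did not pass camera. Among the lists of this paragraph fry called only heat shock and proteolysis (adjusted p = 0.00449) and aromatic amino acid synthesis (0.0246). Of heat shock and proteolysis genes 7 of 15 rose and 4 fell (adjusted p = 0.434), with the chaperone genes clpB (SA0835, 0.57 ± 0.05) and dnaJ (SA1408, 0.54 ± 0.04) higher and clpX (SA1498, -0.46 ± 0.04) lower. Of oxidative and thiol stress genes 4 of 13 rose and 6 fell (adjusted p = 0.701), with a superoxide dismutase gene (SA0128, -1.11 ± 0.06), the ferritin gene ftnA (SA1709, -0.72 ± 0.06) and the peroxide regulator gene perR (SA1678, -0.60 ± 0.04) falling most. In DNA repair and SOS 5 of 19 rose and 7 fell (adjusted p = 0.881), with SA0481 (0.69 ± 0.04), recA (SA1128, 0.53 ± 0.04) and ruvB (SA1467, 0.45 ± 0.05) higher. SA0481 is described as uvrB. It is 567 bp long and its tag lies between those of ctsR (SA0480) and mcsB (SA0482), so its place in this list is doubtful. The list's mean (0.01) lay above 0, its median (-0.05) and test below. Iron acquisition genes rose in 5 of 18 cases and fell in 5 (adjusted p = 0.881), with feoA (SA2338, -1.41 ± 0.28) lower and sbnD (SA0115, 1.05 ± 0.20) and sbnC (SA0114, 0.91 ± 0.15) higher at a few CPM; its test pointed down while its median (0.00) and mean (0.01) were not below 0. In aromatic amino acid synthesis 8 of 16 rose and 5 fell (adjusted p = 0.358), with trpC (SA1202, 1.85 ± 0.17), trpF (SA1203, 1.63 ± 0.20) and trpD (SA1201, 1.51 ± 0.20) higher. In lysine, threonine and methionine synthesis 8 of 14 rose and 4 fell (adjusted p = 0.230), with asd (SA1226, 1.32 ± 0.11) and dapA (SA1227, 1.09 ± 0.12) higher. SA2258 (1.41 ± 0.23), matched as dapF only through its product, diaminopimelate epimerase, rose from 1.01 ± 0.0422 to 2.68 ± 0.249 CPM. It starts at 2535319, away from asd (1401012) and dapA (1402003), so its place in this list is uncertain. Aminoacyl-tRNA synthetase genes rose in 7 of 20 cases and fell in 6 (adjusted p = 0.881), with serS (SA0009, 1.25 ± 0.05) higher and thrS (SA1506, -0.91 ± 0.12) and ileS (SA1036, -0.81 ± 0.06) lower. Of the 57 ribosomal protein genes 21 rose and 15 fell (adjusted p = 0.549); the genes for S20 (SA1414, -1.17 ± 0.06) and L33 (SAS042, -1.15 ± 0.06, and SAS047, -1.10 ± 0.10) fell most, and the list's mean (-0.01) was below 0 while its median (0.13) and test were above. Ribosomal protein genes held 10.6 ± 0.620% of the reads in the controls and 11.3 ± 0.0849% with TTO.

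Stable RNAs, listed as a check of RNA composition, rose in 24 of 72 tested cases and fell in 10 (20 and 9 adjusted over the list alone; camera adjusted p = 0.230). The ribosomal RNA features SArRNA12 (1.66 ± 0.25) and SArRNA15 (1.62 ± 0.26) rose and the transfer RNA feature SAtRNA26 (-2.32 ± 0.33) fell most. Ribosomal RNA copies are near identical, so their separate values are uncertain. Together these RNAs held 0.221 ± 0.0272% of the reads in the controls and 0.303 ± 0.0392% with TTO (SD, n = 2 each). Shares this small do not reflect the RNA of the cells, so they could not serve as a check of its composition.

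**Figure D2:**
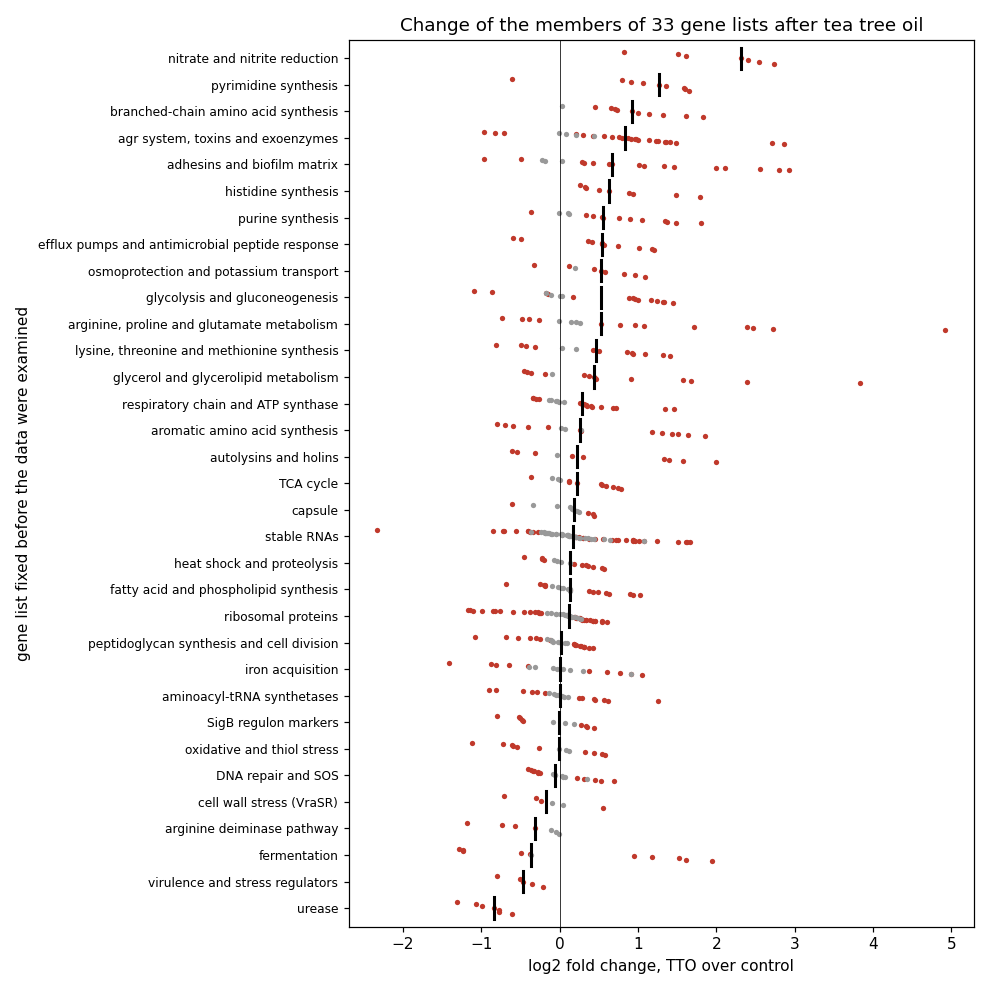
Log2 fold change, TTO over control, of each tested member of the 33 lists (red, called; grey, not called), with a black bar at each list's median. The nitrate and nitrite list had the highest median, 2.31, and urease the lowest, -0.83.

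Of the 33 lists 10 passed camera, 8 higher and 2 lower, and 30 kept the same counts adjusted over the list alone. With an estimated correlation 0 of 33 passed at an adjusted p below 0.05, and the lowest adjusted p was 0.640. At an unadjusted p below 0.05, 0 did (14 with the preset correlation). That setting rests on few residual degrees of freedom. Lists with an estimated correlation near 0 lost their call too, such as branched-chain amino acid synthesis (0.0400) and arginine, proline and glutamate metabolism (-0.0476). Losing every call therefore cannot tell whether correlation between genes made the calls. Fry called 24 of 33 lists moving on balance in a single direction and 32 changing in either direction, without comparing them with other genes.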

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

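The removal of a length trend and the fits on RPKM computed from the counts were chosen after seeing the data; the planned fits on the deposited RPKM were replaced by the latter. Genes called numbered 1886, and 1728 to 1922 under the alternatives that kept all 4 libraries, with 1538 for genes changed by TTO at an adjusted p under 0.01. They were 1578 to 2059 when a library was left out, where the lone library of a group is assumed to vary like the other group. No alternative called a gene of the main result in the opposite direction (0 in each of 14 fits), and the share that rose stayed between 46.9% and 52.0%. Each of these fits scales a library to its own reads, so a steady share cannot tell whether all transcripts shifted together. Genes called at 2-fold or more numbered 359, 290 to 364 with all libraries and 354 to 382 with a library left out. A test against 2-fold itself gave 186, since by construction it asks that the change exceed 2-fold beyond its error. Lists called numbered 10, 9 to 12 with all libraries and 9 to 11 with a library left out, and 0 with an estimated inter-gene correlation (camera; at an unadjusted p under 0.05, 0 with the estimated and 14 with the preset correlation). The estimated correlation had little power at 2 libraries per group, so its 0 does not decide whether correlation between genes made the calls. Median log2 fold changes are given here with adjusted p. The efflux list (0.55, adjusted p = 0.0515) passed with RLE (0.54), total-count scaling (0.52), no filter (0.55), DESeq2 (0.54), limma-voom (0.55), both RPKM fits (0.52 and 0.52) and without D1-2, at 0.0368 to 0.0936 over all 14 and medians of 0.52 to 0.57 with a library left out. The osmoprotection list (0.53, 0.0598) passed with total-count scaling (0.51), both RPKM fits (0.48 and 0.50) and without D1-2, at 0.0459 to 0.151 and 0.46 to 0.59. Stable RNAs passed with the length trend removed (0.37, 0.00329, range to 0.559). The arginine, proline and glutamate list did not pass with upper-quartile scaling (0.54), above a mean of 10 CPM (0.66), with the length trend removed (0.35) or without control 1, at 0.0267 to 0.131 and 0.47 to 0.59; the regulator list did not without D1-1 or D1-2, at 0.0216 to 0.0649 and -0.52 to -0.42. For these lists the cause was not tested. The mean correlation within groups, 0.998, was 0.999 by Spearman's rank. Of the 105 named genes 101 kept their call and direction in the alternatives that tested them; cap5B, cap8F, capA and crtO did not. No paired analysis was possible because the TTO columns carry no replicate number of a sample, so the replicate block was not run. Of 2860 features 179 had too few reads to be tested, 107 of them with 0 reads in all 4 libraries, and whether depth or absence from the strain was the cause was not tested. At this depth and with the spread fitted to these libraries, 52 of 65 simulated changes of 0.5 on the log2 scale were called.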

Other observations

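All tests in this part were chosen after the result was seen, from 19 groups of genes looked at, of which 16 came from words in the product description. Adjusted p are camera's over those 19. They do not correct for choosing groups by their values, so they only describe these data. Sugar uptake genes rose with TTO. The phosphotransferase system (PTS) imports and phosphorylates sugars. Of 19 genes with the word PTS in their description, 17 rose, 10 of them at least 2-fold, and 0 fell. Their median log2 fold change was 1.06 (camera adjusted p = 3.03e-06, and 0.540 with an estimated correlation). Descriptions alone placed genes in this group, so some may not be transporter genes. SA2326, described as a glucoside transporter component, went from 112 ± 14.0 to 1685 ± 42.0 CPM (mean ± SD, n = 2). SA2167, described as a sucrose transporter subunit, went from 75.8 ± 4.56 to 450.3 ± 0.947 CPM. SA0432, described as an ascorbate transporter subunit IIA, went from 164 ± 9.02 to 1176 ± 21.4 CPM. At 1428 bp it is longer than SA0320 (444 bp), which has the same description, so its substrate is uncertain. An adjacent sugar ABC transporter set, SA0206 (5.30 ± 0.11), SA0207 (4.09 ± 0.12) and SA0208 (3.42 ± 0.12), rose too. The gluconate genes SA2295 (3.68 ± 0.08), SA2294 (3.34 ± 0.08) and SA2293 (2.52 ± 0.11), a glucarate transporter gene (SA2300, 3.38 ± 0.09) and a sialic acid lyase gene (SA0304, 2.34 ± 0.16) rose as well.

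Among genes that fell, the abundant hypothetical gene SA2011 (chromosome, 2283982 to 2284611) went from 9821 ± 600.3 to 3167 ± 144 CPM, and SA1233, described as protein msa, went from 52.7 ± 5.04 to 12.7 ± 0.466 CPM. Of 91 tested genes described as transcriptional regulators, 21 rose and 50 fell, with a median of -0.32 (adjusted p = 0.0115; adjusted p = 0.540 with an estimated correlation).

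A prophage rose on 1 strand, though 2 minus-strand genes past its integrase gene rose too, so the rise was not confined to it. These were SA1812 (1.73 ± 0.13), described as gamma-hemolysin subunit B, and SA1813 (2.04 ± 0.10), described as succinyl-diaminopimelate desuccinylase. Whether they rose with the prophage or with the toxin genes was not tested. The prophage was noticed in a running median along the chromosome and then bounded by annotation. Its bounds were the staphylokinase gene and the integrase gene (2009086 to 2049520, 59 features). The staphylokinase gene is also counted in the list of toxins and exoenzymes. On the minus strand, with replication, capsid and tail genes, 44 of 48 rose, 2 fell and the median was 1.20. Camera gave adjusted p = 1.66e-08 (adjusted p = 0.540 with an estimated correlation). The block was picked for its high values. The adjustment over 19 groups covers neither the scan along the chromosome nor the split by strand, so this p-value adds no support. More phage DNA at the same output per copy, as the only cause, was argued against by the plus strand. There 1 of 10 rose, 4 fell and the median was -0.11. The 4 that fell (SA1805, SA1806, SA_RS10380 and SA1807) lie next to each other, and SA_RS10115, SA1800 and SA1809 had under 1 CPM. More phage DNA together with a lower output of plus-strand genes stays open. Gene length was argued against by a minus-strand median of 1.32 once the length trend was removed. An SOS response stays open, since recA (SA1128, 0.53 ± 0.04) rose while lexA (SA1174, -0.28 ± 0.05) fell. The genes uvrA (SA0714, -0.05 ± 0.05) and uvrB (SA0713, 0.04 ± 0.05) did not pass. SA0481 (0.69 ± 0.04), also described as uvrB, rose. It is 567 bp long and its tag lies between those of ctsR (SA0480) and mcsB (SA0482), so it may not be a repair gene. High baselines could hide a response in few cells. A response of the phage genes to TTO by another route and reads from a related prophage of ATCC29213 were not tested and stay open too.

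Short genes were lower with TTO. Over 2609 coding genes, length and log2 fold change had rho = 0.262 across genes, which are not independent replicates; under 300 bp, a line set after the values were seen, 71 rose and 178 fell of 385 (median -0.30), and from 300 bp 852 rose and 751 fell of 2224 (median 0.04). Low counts were argued against by rho of at least 0.145 in each bin of mean CPM, and ribosomal or uncharacterised products by rho = 0.225 over the 1794 other genes. A length-dependent difference between library preparations could not be excluded: rho was 0.121 between the controls and 0.00194 between the TTO libraries, and no label says how the libraries were grouped in preparation.

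Plasmid genes held 0.600 ± 0.00826% of the reads in the controls and 0.307 ± 0.000607% with TTO (SD, n = 2), a gap that an exact permutation test of 2 against 2 could not place below p = 0.333. Of 16 tested plasmid genes 11 fell and 3 rose (camera adjusted p = 0.0557; adjusted p = 0.540 with an estimated correlation). Fewer plasmid copies as the only cause were argued against by the 3 that rose. These were the arsenic resistance genes SAP016 (0.60 ± 0.06), SAP017 (0.61 ± 0.05) and arsC (SAP018, 0.47 ± 0.06). They are adjacent on the same strand, so they may be 1 joint change. The plasmid is that of N315, and 16 of its 28 features were tested. The argument holds only if ATCC29213 carries these genes on the same plasmid, which is not known. Fewer copies together with other changes stay open. The hypothetical gene SAP001, with 63.4% of the CPM of the tested plasmid genes in the controls, went from 3768 ± 224 to 1459 ± 34.4 CPM, but a change of this gene as the only cause was argued against by the 10 of 15 other plasmid genes that fell.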
